A study of Homo sapiens with 3 samples.

How the data were processed

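Counts of antibody-derived DNA barcodes were analysed for HBL1 cells in 3 GEO samples, each a plate library: an unstimulated dose plate, a stimulated dose plate and a combination plate. Per the labels' protocols, cells rested in low-serum medium, received an inhibitor in 1% DMSO for 60 min and then PBS or the stimulus for 20 min, and were fixed and permeabilised before staining overnight. The inhibitors were ibrutinib (iBTK), R406 (iSYK) and QNZ (iNFkB). Doses were 0.1, 1, 10 and 100 µM on the dose plates, and mixtures of 0, 1, 2.5, 5 or 10 µM of each on the combination plate. Mixed conditions are named in the order iSYK+iBTK+iNFkB in µM, so that 10+0+0 is R406 alone at 10 µM. Dose plates held 3 wells per inhibitor and dose and 12 wells each of the vehicles DMSO and PBS; the combination plate held 3 wells per condition.

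The deposited counts are whole numbers of barcode reads per antibody and well, made by the authors with bcl2fastq, kallisto and bustools, per the submitters' processing notes, which give no versions. Whether molecular identifiers were collapsed is not stated. The deposited tables also hold, from the values, a scaling factor per well that is a ratio (the median over antibodies of the count over its geometric mean, within a relative difference of 4.88e-15), and a normalized signal, the deposited counts divided by that factor (within 8.10e-15). The dose tables add a deposited ratio of this signal to the unstimulated mean of the same inhibitor and dose, and its deposited log2 value. The 111 antibodies of the antibody table all appeared on the combination plate and 107 on the dose plates. By their names 59 of the 107 bind phosphorylated or cleaved forms and 48 total proteins, against 62 and 49 of the 111.

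Everything else was computed from the deposited counts. Antibodies needed at least 10 counts in at least 3 wells and wells at least 1000 counts, which removed 0 antibodies and 0 wells. Counts were scaled by TMM factors over all antibodies and tested in edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood fit over all wells of a plate, or of both dose plates for stimulus effects and differences between plates. Adjusted p-values are Benjamini-Hochberg over the antibodies of a comparison, with 0.05 as the threshold. Dose effects were tested by an F-test over the 4 doses against the DMSO wells and by a contrast per dose, and the direction of an F-test call is the sign at 10 µM. Inhibitors were contrasted with each other at each dose, the vehicles with each other, each combination with DMSO, 10 µM of each with each single inhibitor at 10 µM, and 10 µM of each with the sum of the single log2 effects. These comparisons, the lists and the rule for naming antibodies were fixed before the data were examined. Contrasts of mixtures with each other, the contrast with unstimulated DMSO wells, the stimulus effect under the mixture and the difference between its stimulated and unstimulated effects were added later.

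Antibodies are named in the text by a rule: up to 8 that fell and 8 that rose most at 10 µM among those past the threshold and moving the same way in every well of that dose, and 10 each way for the stimulus, 5 each way for differences between plates and departures, and members of the BCR and NF-kB lists. Of 11 lists with at least 3 members, fixed by target name, shifts against all other antibodies were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists and contrasts of a family (264 tests for dose effects, 22 for the stimulus and 319 on the combination plate). They were BCR proximal (14 antibodies), MAPK (11 on the dose plates, 12 on the combination plate), PI3K-AKT-mTOR (9, 10), NF-kB (5, 6), JAK-STAT (7), cell cycle (13), DNA damage and apoptosis (6, 7), B-cell identity (7), controls (4: 2 isotype antibodies, Histone H3 and GAPDH), phospho-specific or cleaved (59, 62) and total protein (48, 49). Other planned lists had too few members. Total counts per well were compared by exact two-sided permutation of their log10 values.

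The residual degrees of freedom were 54 on each dose plate, 108 for both and 30 on the combination plate. The median count per antibody and well was 1585, 1476 and 1479, and counting error of a well is therefore near the spread between wells. Between wells of a condition, the median chi-square per degree of freedom was 1.66, 1.93 and 2.04, with 33 of 180, 19 of 180 and 6 of 45 pairs of wells at p above 0.05, and 0 pairs were identical. On data simulated from the real means with 20 changed antibodies in each of 20 runs, the test of the ibrutinib doses in stimulated cells called 68.0% of antibodies changed 1.1-fold and 100% of those changed 1.25-fold, and 1.15% of the unchanged. For the departure from the sum these were 13.0%, 78.0% and 0.385%.

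Alternatives were DESeq2 1.42.0 (Wald or likelihood-ratio tests), its median-of-ratios factors in edgeR, total counts only, scaling on total-protein antibodies, limma on the deposited normalized signal (log2 after adding 1), filters, replicate number as a block, the left or right side of the plate, PBS wells as control, only the compared conditions in the fit, each replicate left out, and no 100 µM wells. Added after the data were seen were the 3 DMSO wells in the inhibitor's own plate columns, plate column as a block, the log10 total as a covariate, and no wells under 0.5 of the plate median. Left out of the comparisons were 2 further plates (144 wells) of another cell line in the dose table, which match no GEO sample, and the 12 wells per plate of an inhibitor named iPI3Kd, which the labels' protocols do not describe.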

Results

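Antibody-derived barcode counts were obtained from HBL1 cells, an established line of the activated B-cell-like type of diffuse large B-cell lymphoma, in 3 plate libraries. The measurement, immunodetection by sequencing (ID-seq), stains fixed and permeabilised cells with DNA-barcoded antibodies and counts the barcodes per antibody and well. Cells received ibrutinib (iBTK, an inhibitor of the kinase BTK), R406 (iSYK, an inhibitor of the kinase SYK) or QNZ (iNFkB, an inhibitor of NF-kB activation) for 60 min. They were then given PBS or a stimulus of 15 µg/mL anti-immunoglobulin F(ab')2 fragments with 15 mM hydrogen peroxide for 20 min. The unstimulated and the stimulated dose plate held 72 wells each, with 3 wells for every inhibitor at 0.1, 1, 10 and 100 µM and 12 wells for each of the vehicles DMSO and PBS, and measured 107 antibodies. The combination plate held 45 wells in triplicate conditions, 39 stimulated and 6 unstimulated, and measured 111 antibodies.

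Total counts per well had a mean of 206159 (range 51056 to 304286) on the unstimulated dose plate, 199934 (67471 to 300776) on the stimulated dose plate and 214609 (65432 to 333162) on the combination plate. The biological coefficient of variation between wells of a condition was 2.79% and 2.51% on the dose plates and 2.89% on the combination plate. Nothing in the labels says that wells of a condition came from separate cultures, so p-values measure the spread between wells, which may be technical. Errors after ± are standard errors of the fitted log2 change, with 3 wells per inhibitor condition, 12 DMSO wells on each dose plate and 3 DMSO wells per stimulus on the combination plate. On the dose plates conditions were nested in plate rows. A contrast of a dose with DMSO therefore also compares rows, while inhibitors at the same dose shared a row.

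The stimulus comparison asked which proteins and sites responded to receptor ligation with peroxide in DMSO-treated cells. On the dose plates the largest rises were those of VAV1 (Y174) by 1.83 ± 0.027 log2 and of BTK (Y551), the activation-loop site of BTK, by 1.47 ± 0.025. PYK2 (Y402), a focal adhesion-related kinase, rose by 1.03 ± 0.028 and BLNK (SLP-65) (Y84), the adaptor between SYK and BTK, by 1.00 ± 0.018. LYN (SRC) (Y397) rose by 0.90 ± 0.021, JAK1 (Y1022/Y1023) by 0.79 ± 0.022, SRC (Y416) by 0.75 ± 0.016, CDK1 (T14/Y15) by 0.69 ± 0.019, CD79a (Iga) (Y182) by 0.63 ± 0.028 and BTK (Y223), the BTK autophosphorylation site, by 0.57 ± 0.025. CDC2 (Y15), another antibody to a site of CDK1, went the other way at -0.089 ± 0.016. Other falls were PI3K p110d (PIK3CD) at -0.16 ± 0.037, c-FOS (S32) at -0.15 ± 0.023 and PKC-b1 (T642) at -0.12 ± 0.011. In all 62 of 107 antibodies changed, 33 higher and 29 lower (edgeR, adjusted p under 0.05). DESeq2 called 65.

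Of the 14 antibodies on the proximal B-cell receptor (BCR) list, 11 rose and 1 fell with the stimulus, with the same counts adjusted over the list alone and a median change of 0.54 log2 (camera adjusted p = 3.3e-08). Among MAPK antibodies 5 of 11 rose and 2 fell (5 and 3 adjusted over the list alone), led by MAPK p38 (T180/Y182) at 0.30 log2, and of the cell cycle list 1 of 13 rose and 8 fell. The PI3K-AKT-mTOR list had 2 rises and 4 falls among 9, NF-kB 0 and 2 among 5, JAK-STAT 2 and 1 among 7, DNA damage and apoptosis 2 and 0 among 6, and B-cell identity 2 and 3 among 7 (2 and 4 adjusted over the list alone). Phospho-specific or cleaved forms rose in 23 of 59 cases and fell in 14, total proteins rose in 10 of 48 and fell in 15, and of the 4 control antibodies GAPDH rose by 0.22 ± 0.017. With scaling on total counts only, 18 antibodies were higher and 83 lower, the phospho-specific list turned to 14 higher and 41 lower, and the MAPK list to 1 and 8, while GAPDH kept its sign but went from 0.22 to 0.088. Stimulus and plate are the same split of the dose plates, so they cannot be told apart there.

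The combination plate held stimulated and unstimulated DMSO wells side by side. There VAV1 (Y174) rose by 2.19 ± 0.065 log2, BTK (Y551) by 1.58 ± 0.061, PYK2 (Y402) by 1.29 ± 0.057, BLNK (SLP-65) (Y84) by 1.05 ± 0.039 and LYN (SRC) (Y397) by 1.00 ± 0.043. JAK1 (Y1022/Y1023) rose by 0.89 ± 0.038, CD79a (Iga) (Y182) by 0.85 ± 0.049, SRC (Y416) by 0.80 ± 0.037, BTK (Y223) by 0.73 ± 0.057 and CDK1 (T14/Y15) by 0.59 ± 0.041. Cyclin D1 fell by 0.22 log2 and Cyclin B1 by 0.21, c-MYC (T58) by 0.16 and c-FOS (S32) by 0.15. Of 111 antibodies 45 changed, 26 higher and 19 lower, and DESeq2 called 44. The BCR list had 10 rises and 1 fall (11 and 1 adjusted over the list alone; camera adjusted p = 1.7e-07). With total counts only the split was 20 higher and 71 lower, and the median of all antibodies moved by 0.130 log2, the largest shift of any scaling in any comparison; with scaling on total-protein antibodies it was 31 and 11. Across the 107 antibodies shared by both experiments, which are not independent replicates, the stimulus effects correlated with Pearson's r = 0.981 and Spearman's rho = 0.772, and 37 antibodies were called in both, 25 higher and 12 lower, with 0 in opposite directions.

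**Figure D1:**
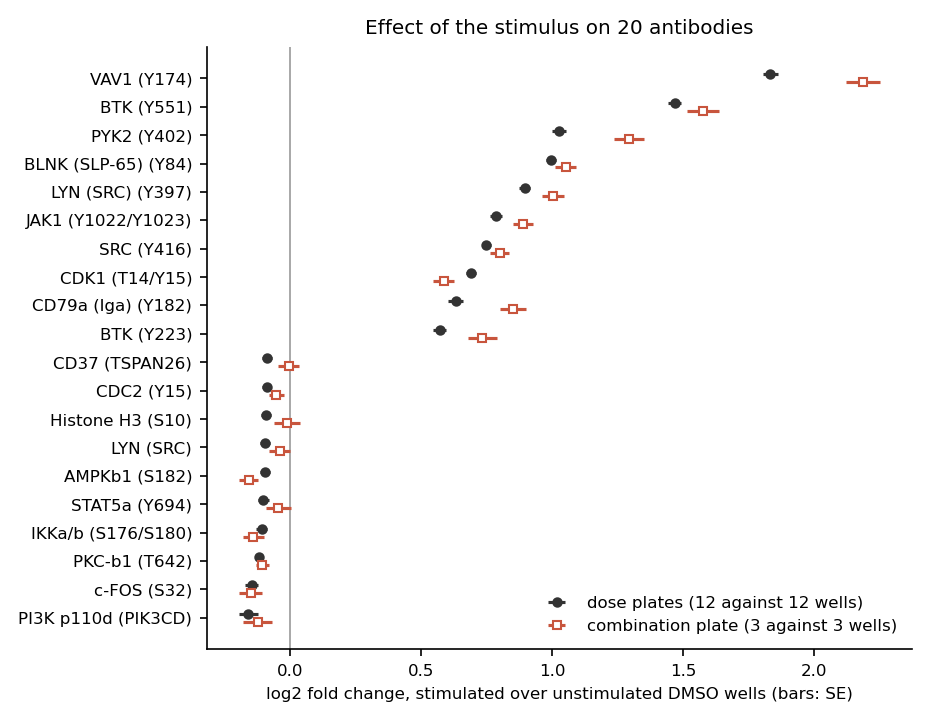
Log2 change with the stimulus in DMSO-treated cells for 20 antibodies, measured on the dose plates and on the combination plate, with bars of ± 1 standard error. VAV1 (Y174) has the largest rise in both, 1.83 and 2.19, and BTK (Y551) follows at 1.47 and 1.58.

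The dose plate without stimulus asked what each inhibitor did to resting cells, a term used here for cells not given the stimulus. The sample title names this plate basal signaling, and whether signalling was silent in these cells was not tested. Under ibrutinib at 10 µM the phosphorylated ribosomal protein S6, a target of the mTOR and S6 kinase pathway, fell by 0.27 ± 0.040 log2 at S6 (S240/S244) (adjusted p = 3.4e-07) and by 0.22 ± 0.037 at S6 (S235/S236). ATF2 (T71), a transcription factor phosphorylated by stress kinases, fell by 0.17 ± 0.041. At 100 µM these were -0.40, -0.36 and -0.21, and IgM rose by 0.30 ± 0.061 and GAPDH by 0.14 ± 0.022. The F-test over the 4 doses called 11 of 107 antibodies; taking the direction of a call from the sign at 10 µM, here and below, 4 were higher and 7 lower. Only 3 of the 11, the 2 S6 sites and ATF2 (T71), passed the threshold at 10 µM itself; the other 8, with all 4 of the higher ones, did not, among them CREB (S133) at -0.08 ± 0.030 log2 and GAPDH at 0.02 ± 0.021. At 0.1 and at 1 µM edgeR called 0 antibodies, with 4 and 17 at an unadjusted p under 0.05 and 0 by DESeq2 at either dose. Of 9 PI3K-AKT-mTOR antibodies 2 fell at 10 µM, both S6 sites (camera adjusted p = 0.0019), and 0 of 14 BCR antibodies changed there. The count was 3 without replicate 1 and 4 without replicate 2, and the split was 3 higher and 10 lower with scaling on total-protein antibodies, 3 and 9 with DESeq2 and 4 and 4 with limma on the deposited normalized values.

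R406 lowered the same S6 sites in resting cells, by 0.38 ± 0.038 log2 at S6 (S235/S236) (adjusted p = 1.8e-12) and 0.36 ± 0.042 at S6 (S240/S244) at 10 µM. ATF2 (T71) fell by 0.17 ± 0.042 and CREB (S133), a transcription factor activated by several kinases, by 0.16 ± 0.032. BTK (Y551) fell by 0.10 ± 0.033 and VAV1 (Y174) by 0.08 ± 0.027, while LYN (SRC) (Y397) rose by 0.08 ± 0.024 and GAPDH by 0.10 ± 0.022. Without the 1 DMSO well under 0.25 of the plate median total, BTK (Y551) and VAV1 (Y174) lost their calls at -0.090 and -0.075 (adjusted p = 0.0616 for each). CREB (S133) was the sole call at 1 µM, -0.15 ± 0.032, chosen after its value was seen. The F-test called 10 antibodies, 2 higher and 8 lower. In the BCR list 1 rose and 2 fell at 10 µM, in the PI3K-AKT-mTOR list 0 and 2 (camera adjusted p = 0.04), and in the MAPK list 0 and 2. BIM was counted as lower by its value of -0.02 ± 0.168 at 10 µM but passed through 1 of the 3 wells at 100 µM, where the fitted change was 0.99 ± 0.149. At 0.1 µM edgeR and DESeq2 called 0 antibodies, with 10 at an unadjusted p under 0.05. The F-test count was 18 against the 3 DMSO wells in the same plate columns and 16 without wells under 0.5 of the plate median total.

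QNZ changed more antibodies in resting cells at its highest dose than at 10 µM. At 100 µM Histone H2A.X (S139), the mark of DNA breaks, rose by 0.61 ± 0.038 log2, AKT (S473) by 0.22 ± 0.049 and GAPDH by 0.27 ± 0.023. Of the other controls Isotype Rabbit IgG fell by 0.17 ± 0.038 and Histone H3 by 0.16 ± 0.038. S6 (S235/S236) fell by 0.54 ± 0.041, ATF2 (T71) by 0.46 ± 0.047, AMPKa1/2 (T183/T172), an energy-sensing kinase, by 0.44 ± 0.027, LYN (SRC) (Y397) by 0.40 ± 0.028 and CREB (S133) by 0.29 ± 0.035. At 10 µM JNK1/2 (SAPK) (T183/Y185) fell by 0.18 ± 0.045, SYK by 0.17 ± 0.036, CD27 by 0.14 ± 0.042 and LYN (SRC) by 0.12 ± 0.034, while PLCy2 (Y759) rose by 0.18 ± 0.037 and Cyclin B1 by 0.14 ± 0.041. Of the NF-kB list TAK1 (T184/T187), a kinase upstream of IKK, fell at 10 µM by 0.11 ± 0.035 (-0.096, adjusted p = 0.0511, without the DMSO well of lowest total) and the other 4 members did not pass. The F-test called 61 antibodies, 29 higher and 32 lower, of which 9 of 14 on the BCR list (5 higher, 4 lower), 7 of 11 on the MAPK list (3 and 4) and 3 of 6 on the DNA damage and apoptosis list (2 and 1). Per dose the counts were 0 at 0.1 µM (3 at an unadjusted p under 0.05, 0 by DESeq2), 1 at 1 µM (ATF2 (T71), 0.19 ± 0.040, chosen after its value was seen), 13 at 10 µM and 55 at 100 µM. Without the 100 µM wells the F-test called 14, and limma on the deposited normalized values called 40 higher and 29 lower. The 13 calls at 10 µM became 0 without replicate 2, 6 without replicate 3 and 3 with only the compared conditions in the fit, but 25 with limma, 36 with PBS wells as control, 34 with both vehicles and 25 with own DMSO wells.

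In stimulated cells ibrutinib lowered BTK (Y223) by 0.62 ± 0.045 log2 at 10 µM (adjusted p = 5.5e-19), SRC (Y416) by 0.59 ± 0.029 and LYN (SRC) (Y397) by 0.58 ± 0.042. CDK1 (T14/Y15) fell by 0.30 ± 0.033, BTK (Y551) by 0.30 ± 0.046, SYK (Y525/Y526) by 0.29 ± 0.051, PYK2 (Y402) by 0.27 ± 0.047 and VAV1 (Y174) by 0.25 ± 0.053. The kinase sites were lower than in DMSO from the lowest dose, with BTK (Y223) at -0.41, -0.47, -0.62 and -0.55 and SRC (Y416) at -0.42, -0.57, -0.59 and -0.73 log2 over 0.1, 1, 10 and 100 µM. VAV1 (Y174) went from -0.25 at 10 µM to -1.41 ± 0.061 at 100 µM and BLNK (SLP-65) (Y84) from -0.21 to -0.88 ± 0.035. Rises at 10 µM were small, with total PLCy2, the phospholipase downstream of BTK, at 0.12 ± 0.023 and CD79a (Iga) at 0.11 ± 0.023.

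The F-test for ibrutinib in stimulated cells called 40 antibodies, 18 higher and 22 lower, and DESeq2 called 33. At 10 µM 11 of 14 BCR antibodies fell and 0 rose (12 adjusted over the list alone; camera adjusted p = 7.9e-12), and of the NF-kB list 0 of 5 passed. The MAPK and PI3K-AKT-mTOR lists had 2 falls each and the cell cycle list 1 rise and 1 fall. At 0.1 µM already 11 BCR antibodies fell (12 adjusted over the list alone; camera adjusted p = 1e-13). MAPK p38 (T180/Y182) fell by 0.16 log2 at 10 µM and 0.27 at 100 µM, and S6 (S235/S236) by 0.18 and 0.32. The calls split as 7 higher and 27 lower with scaling on total-protein antibodies, 11 and 23 with median-of-ratios factors, 11 and 22 with DESeq2, 12 and 26 with limma and 71 and 21 with total counts only.

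R406 lowered a partly different set of sites most in stimulated cells, led at 10 µM by VAV1 (Y174) at -0.77 ± 0.055 log2 (adjusted p = 1.3e-18), BTK (Y551) at -0.65 ± 0.048 and BLNK (SLP-65) (Y84) at -0.63 ± 0.033. LYN (SRC) (Y397) fell by 0.60 ± 0.041, SRC (Y416) by 0.58 ± 0.028, JAK1 (Y1022/Y1023) by 0.57 ± 0.038, PYK2 (Y402) by 0.52 ± 0.048 and BTK (Y223) by 0.50 ± 0.044. VAV1 (Y174) read -0.26, -0.55, -0.77 and -0.83 over the 4 doses and BLNK (SLP-65) (Y84) -0.16, -0.41, -0.63 and -0.63. Rises at 10 µM reached 0.14 ± 0.023 for PLCy2 and 0.12 ± 0.030 for AMPKb1 (S182), and at 100 µM the controls Isotype Rabbit IgG and GAPDH rose by 0.14 and 0.17. Of the BCR list 11 of 14 fell at 10 µM and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.6e-07). From the NF-kB list IkB, the inhibitor protein of NF-kB, rose by 0.11 ± 0.031 and the other 4 members did not pass. The phospho-specific list had 4 rises and 20 falls of 59 (27 and 16 with total counts only), and the MAPK list 1 and 3 (5 and 2 with total counts only). The F-test called 42 antibodies, 20 higher and 22 lower, and DESeq2 45. That split was 9 and 30 with scaling on total-protein antibodies, 15 and 25 with limma and 73 and 17 with total counts only; at 1 µM 30 antibodies changed, 19 without replicate 3 and 12 against the 3 DMSO wells in the same columns.

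QNZ lowered BTK (Y223) by 0.64 ± 0.050 log2 (adjusted p = 6.5e-18), LYN (SRC) (Y397) by 0.62 ± 0.044, VAV1 (Y174) by 0.60 ± 0.058, SRC (Y416) by 0.50 ± 0.030, BLNK (SLP-65) (Y84) by 0.48 ± 0.035 and BTK (Y551) by 0.46 ± 0.051 in stimulated cells at 10 µM. Most of this was present at 0.1 µM, where BLNK (SLP-65) (Y84) was already at -0.44 ± 0.032, LYN (SRC) (Y397) at -0.48 ± 0.040 and VAV1 (Y174) at -0.41 ± 0.052. AKT (S473) rose by 0.19 ± 0.055, AKT (T308) by 0.17 ± 0.039 and STAT6 (Y641) by 0.16 ± 0.039 at 10 µM. At 100 µM VAV1 (Y174) reached -1.34 ± 0.060 and LYN (SRC) (Y397) -1.13 ± 0.045, while Histone H2A.X (S139) rose by 0.42 ± 0.034 and cleaved Caspase 3 (D175), an executioner of apoptosis, by 0.20 ± 0.031. Of the controls GAPDH was at -0.12 at 10 µM and 0.14 at 100 µM and Histone H3 at -0.14 at 100 µM. With total counts only in edgeR, GAPDH at 10 µM (-0.055, adjusted p = 0.10) and Histone H3 (-0.041, adjusted p = 0.29) lost their calls. GAPDH at 100 µM was then at 0.24. With scaling on total-protein antibodies all 3 values kept their calls. Of the BCR list 10 of 14 fell at 10 µM and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 2.8e-06), and 11 fell at 0.1 µM. The MAPK list had 6 falls of 11, among them MAPK p38 (T180/Y182) at -0.26 and CREB (S133) at -0.18 log2, and the NF-kB list 0 of 5 past the threshold at 10 µM. The stimulus itself had raised 0 of these 5 and lowered 2. The list therefore held no called rise to remove and does not show whether QNZ spared NF-kB. The F-test called 79 antibodies, 40 higher and 39 lower, and DESeq2 76. The split was 22 and 41 with scaling on total-protein antibodies and 74 and 24 with total counts only, and the F-test count was 46 without the 100 µM wells.

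**Figure D2:**
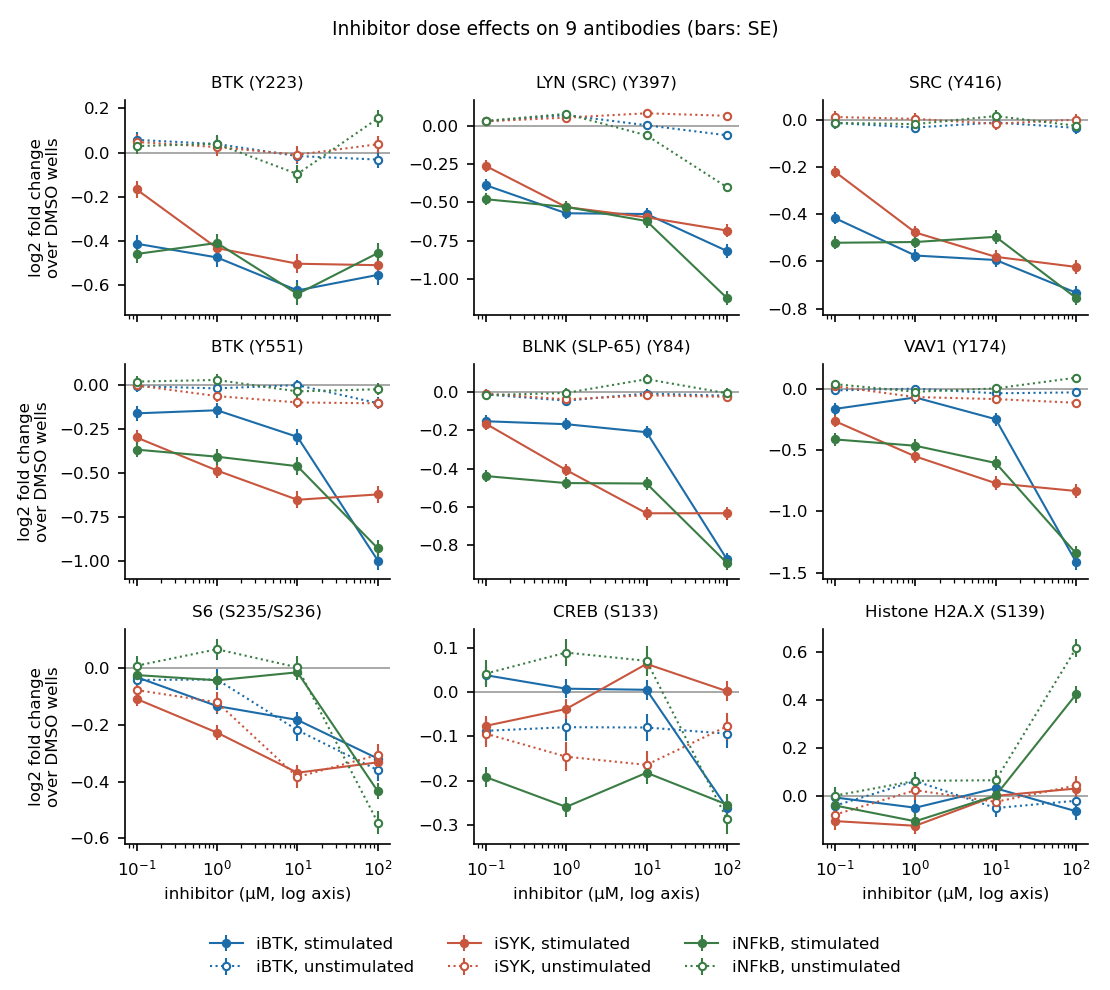
Log2 change against DMSO over inhibitor dose (µM, log axis) for 9 antibodies, with a line per inhibitor, solid on the stimulated and dotted on the unstimulated plate, and bars of ± 1 standard error. On the stimulated plate VAV1 (Y174) reaches -1.41 under ibrutinib and -1.34 under QNZ at 100 µM, and Histone H2A.X (S139) rises under QNZ by 0.42 there and 0.61 without stimulus.

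At 10 µM the 3 inhibitors shared most of their falls in stimulated cells. There 14 antibodies fell under all 3, where independent lists drawn from all 107 antibodies would share 0.723. Sites raised by the stimulus have the most room to fall, so an overlap above that value does not by itself show a shared action. Pairwise, 16 of the 18 falls under ibrutinib and the 20 under R406 coincided (3.36 for independent lists), 15 for ibrutinib and QNZ (3.87) and 16 for R406 and QNZ (4.30). Rises at 10 µM numbered 4 under ibrutinib, 14 under R406 and 15 under QNZ, with 2 common to all 3. At 100 µM 16 falls were common to all 3, of 24, 18 and 34 in the same order. The comparisons used the same DMSO wells. Unchanged groups simulated against these wells shared 0 calls, which concerns false calls only. With the DMSO wells split between the inhibitors the overlaps in falls at 10 µM were 16, 15 and 16.

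Whether an inhibitor's log2 effect differed with and without the stimulus was tested as the difference between the plates' changes, which cancels an additive plate effect. Sites raised by the stimulus had more room to fall in stimulated cells. A more negative change there does not by itself show a different action of the inhibitor, here or for the mixture below. The ibrutinib effect was more negative in stimulated cells for BTK (Y223), by 0.62 ± 0.058 log2 at 10 µM, SRC (Y416), LYN (SRC) (Y397) and CDK1 (T14/Y15), with 23 antibodies called over the doses (5 higher, 18 lower). For R406 the difference was largest at VAV1 (Y174), -0.72 ± 0.064, and LYN (SRC) (Y397), -0.71 ± 0.048, with 22 called (3 and 19). Here CREB (S133) went the other way by 0.20 ± 0.040, having fallen in resting cells. For QNZ it was largest at VAV1 (Y174), -0.64 ± 0.070, and LYN (SRC) (Y397), -0.59 ± 0.052, with 24 called, all lower. Of the BCR list 12, 11 and 10 of 14 antibodies were more negative under ibrutinib, R406 and QNZ (13, 12 and 11 adjusted over the list alone, with 1 rise for QNZ; camera adjusted p = 1.8e-11, 5.1e-10 and 5.1e-10 at 10 µM). With total counts only the splits were 46 higher and 19 lower, 45 and 15, and 62 and 15, and limma on the deposited normalized values gave 5 and 16 for R406.

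Against each other at the same dose, the inhibitors separated by site in stimulated cells. The antibodies named in this comparison were chosen after their values were seen. At 10 µM R406 left VAV1 (Y174) lower than ibrutinib did by 0.52 ± 0.068 log2, BLNK (SLP-65) (Y84) by 0.43 ± 0.041, JAK1 (Y1022/Y1023) by 0.42 ± 0.048 and BTK (Y551) by 0.36 ± 0.060. ZAP70 (Y319) was higher under R406 by 0.12 ± 0.033. At 100 µM the order of VAV1 (Y174) turned, with R406 above ibrutinib by 0.58 ± 0.075. QNZ against ibrutinib at 10 µM gave VAV1 (Y174) -0.36 ± 0.071 and CREB (S133) -0.19 ± 0.031, with AKT (S473) at 0.24 ± 0.069 and S6 (S235/S236) at 0.17 ± 0.036. R406 against QNZ gave S6 (S235/S236) -0.35 ± 0.036 and JAK1 (Y1022/Y1023) -0.32 ± 0.051, with CREB (S133) at 0.25 ± 0.031 and ZAP70 (Y319) at 0.20 ± 0.034.

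Over the doses, 25 antibodies differed between R406 and ibrutinib in stimulated cells (9 higher, 16 lower under R406), 57 between QNZ and ibrutinib (23 higher, 34 lower under QNZ) and 60 between R406 and QNZ (31 higher, 29 lower under R406). The BCR list was higher under R406 than under QNZ at 0.1 µM, with 6 of 14 antibodies (8 adjusted over the list alone; camera adjusted p = 4.8e-08). It was higher than under ibrutinib at 100 µM, with 6 antibodies (7 adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.063 with an estimated correlation). In resting cells the counts were 6 (3 and 3), 51 (19 and 32) and 43 (23 and 20). At 0.1 µM there edgeR called 0 in each pair, with 3, 2 and 7 antibodies at an unadjusted p under 0.05 and 0, 0 and 1 by DESeq2. For R406 against ibrutinib at 1 µM edgeR and DESeq2 called 0, with 6 at an unadjusted p under 0.05. Without replicate 2 the stimulated counts were 16, 35 and 37 and the resting counts 1, 28 and 27; QNZ against ibrutinib gave 37 in stimulated cells without replicate 3 and 33 in resting cells without replicate 1, and R406 against ibrutinib in resting cells 2 without replicate 1 and 1 without replicate 3. In stimulated cells the splits became 18 and 14, 31 and 29, and 35 and 31 with total counts only, and 8 and 21, 32 and 30, and 21 and 30 with scaling on total-protein antibodies. Median-of-ratios factors gave 32 and 30 for QNZ against ibrutinib. In resting cells total-protein scaling gave 3 and 5, 30 and 23, and 19 and 27, and for QNZ against ibrutinib median-of-ratios factors and DESeq2 gave 24 and 26 and limma 30 and 23, while limma called 0 and 1 for R406 against ibrutinib.

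In stimulated cells 4 antibodies, all named here, were higher in DMSO than in PBS wells. Conditions are nested in plate rows, so vehicle and row cannot be told apart in this contrast. The same holds for dose and row in the contrasts of a dose with DMSO. CD79a (Iga) (Y182) rose by 0.11 ± 0.025 log2 (adjusted p = 0.0035), JAK1 (Y1022/Y1023) by 0.09 ± 0.021, BTK (Y551) by 0.09 ± 0.027 and SRC (Y416) by 0.07 ± 0.016, with 12 wells per vehicle. Mean totals per well were 194263 (SD 33857) in DMSO and 252103 (SD 33667) in PBS, and with the log10 total as a covariate 2 antibodies were called. On the BCR list 3 rose (6 adjusted over the list alone; camera adjusted p = 0.015, adjusted p = 0.36 with an estimated correlation). In resting cells edgeR and DESeq2 called 0 antibodies, with 8 at an unadjusted p under 0.05, and edgeR called 1 without replicate 3. In stimulated cells the count was 0 without replicate 2 and 0 without replicate 3, and the split was 3 higher and 2 lower with scaling on total-protein antibodies, 4 and 1 with median-of-ratios factors and 4 and 3 with total counts only.

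The combination plate asked how far mixtures of the inhibitors lowered the stimulated state. With 10 µM of each inhibitor VAV1 (Y174) fell by 2.24 ± 0.066 log2 against stimulated DMSO wells (adjusted p = 2.2e-28), with BTK (Y551) at -1.53 ± 0.061, PYK2 (Y402) at -1.26 ± 0.056, BLNK (SLP-65) (Y84) at -1.11 ± 0.039 and JAK1 (Y1022/Y1023) at -1.05 ± 0.039. S6 (S240/S244) fell by 0.89 ± 0.081, LYN (SRC) (Y397) by 0.89 ± 0.043, SRC (Y416) by 0.86 ± 0.037, CD79a (Iga) (Y182) by 0.84 ± 0.049 and BTK (Y223) by 0.73 ± 0.057. IgM rose by 0.36 ± 0.085, total PKC-b1 by 0.26 ± 0.040, CD79a (Iga) by 0.25 ± 0.026, PLCy2 by 0.24 ± 0.041 and PARP (D214), the form cleaved in apoptosis, by 0.15 ± 0.047. Of 111 antibodies 44 changed, 20 higher and 24 lower, and DESeq2 called 42.

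Among the lists, 11 of 14 BCR antibodies fell with 10 µM of each and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.7e-09). The MAPK list had 1 rise and 5 falls of 12, JAK-STAT 1 and 2 of 7, cell cycle 1 and 2 of 13, DNA damage and apoptosis 3 and 0 of 7, B-cell identity 2 and 0 of 7, controls 2 and 0 of 4, and NF-kB 0 of 6. From the PI3K-AKT-mTOR list 2 rose and 3 fell of 10. All 24 falls were of the 62 phospho-specific or cleaved forms, of which 5 rose, and of 49 total proteins 15 rose and 0 fell. With total counts only 63 antibodies were higher and 19 lower, the phospho-specific list turned to 22 and 19, PI3K-AKT-mTOR to 4 and 2, JAK-STAT to 3 and 1 and cell cycle to 6 and 1. With scaling on total-protein antibodies 7 were higher and 35 lower, and both control calls were lost, with GAPDH going from 0.13 ± 0.042 to 0.07 (adjusted p = 0.178) and Histone H3 from 0.11 to 0.056 (adjusted p = 0.285).

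Lower mixed doses went the same way. VAV1 (Y174) fell, with -1.57 ± 0.060 log2 at 1 µM of each and -1.88 ± 0.061 at 2.5 µM of each, as did BTK (Y551), -1.03 and -1.31, and BLNK (SLP-65) (Y84), -0.75 and -1.01. Among mixtures with 5 µM of an inhibitor and 1 µM of the others, VAV1 (Y174) read -2.01 ± 0.063 with R406 at 5 µM, -1.56 ± 0.060 with ibrutinib and -1.71 ± 0.065 with QNZ at 5 µM. Among pairs at 2.5 µM it read -1.22 ± 0.058 for R406 with ibrutinib, -1.66 ± 0.060 for R406 with QNZ and -1.19 ± 0.059 for ibrutinib with QNZ. Alone at 10 µM on this plate it was -0.96 ± 0.058 with R406, -0.52 ± 0.057 with ibrutinib and -0.95 ± 0.058 with QNZ. Of the BCR list 11 antibodies fell and 0 rose in each of these 8 mixtures and pairs except R406 with QNZ and ibrutinib with QNZ, where 12 fell, with the same counts adjusted over the list alone. R406 alone lowered 12 (13 adjusted over the list alone), and ibrutinib and QNZ alone 11 each (12 each adjusted over the list alone).

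Counts of changed antibodies were 27 with 1 µM and 33 with 2.5 µM of each. They were 38, 31 and 41 with 5 µM of R406, ibrutinib or QNZ in the mixture, and 27, 30 and 28 for the pairs R406 with ibrutinib, R406 with QNZ and ibrutinib with QNZ. The singles gave 32, 20 and 21. The F-test over the equal mixtures called 37, 14 higher and 23 lower, and 3 and 27 with scaling on total-protein antibodies or 68 and 20 with total counts only. The mixture with 5 µM QNZ gave 26 without replicate 2 and 26 without replicate 3. Stimulated DMSO wells had the highest mean total of the plate, 327158 against 175981 in unstimulated DMSO wells and 177447 with 10 µM of each, and the smallest p that 3 wells against 3 allow in the exact permutation test, 0.1, was reached for every condition.

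**Figure D3:**
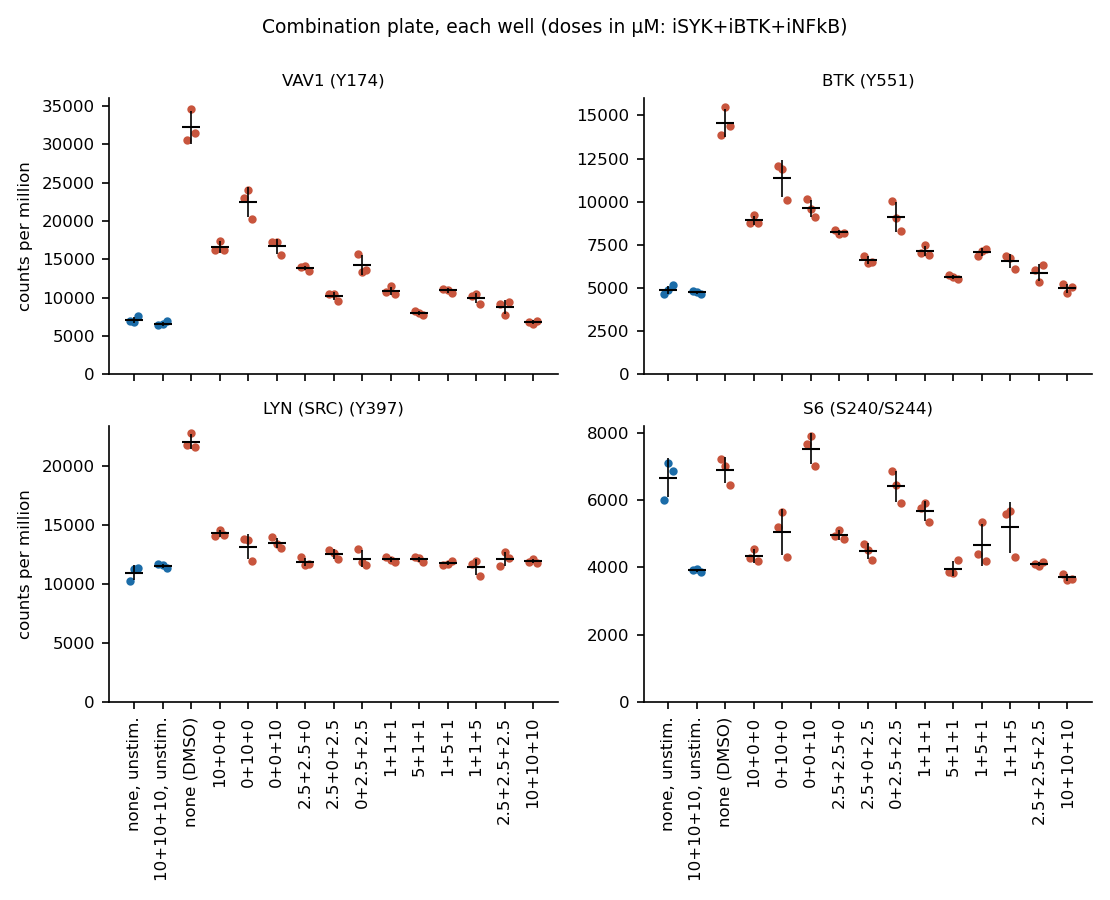
Scaled counts (CPM) per well on the combination plate for VAV1 (Y174), BTK (Y551), LYN (SRC) (Y397) and S6 (S240/S244) in 15 conditions of 3 wells, with the mean and a bar of ± 1 SD. VAV1 (Y174), log2 change -2.24 with 10 µM of each inhibitor, lies near the unstimulated DMSO wells there.

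Adding the missing inhibitor to a pair was tested at 2.5 µM; these contrasts, and those between mixtures, were chosen after the values were seen. Adding QNZ to R406 with ibrutinib lowered 9 antibodies, among them VAV1 (Y174) by 0.66 ± 0.064 log2 and BLNK (SLP-65) (Y84) by 0.55. Adding R406 to ibrutinib with QNZ lowered 8, among them VAV1 (Y174) by 0.69 ± 0.065, S6 (S240/S244) by 0.63 and BTK (Y551) by 0.62. Adding ibrutinib to R406 with QNZ changed 0 by edgeR and by DESeq2, with 7 at an unadjusted p under 0.05 and 4 BCR antibodies lower when adjusted over the list alone (camera adjusted p = 0.012 for that list). With total counts only, adding QNZ raised 3 and lowered 9. Without replicate 1 the counts for QNZ and R406 were 14 and 14, and without replicate 3 that for ibrutinib was 2. R406 at 5 µM against ibrutinib at 5 µM in the mixture lowered 4, namely VAV1 (Y174) by 0.45 ± 0.069, BTK (Y551) by 0.33, BLNK (SLP-65) (Y84) by 0.31 and CD79a (Iga) (Y182) by 0.23, and 11 with those conditions alone in the fit. Against QNZ at 5 µM it lowered S6 (S240/S244) by 0.36, VAV1 (Y174) by 0.30, BLNK (SLP-65) (Y84) by 0.29 and CD79a (Iga) (Y182) by 0.21 and raised GAPDH by 0.18, with 2 calls without replicate 1 and 1 without replicate 2. QNZ against ibrutinib at 5 µM lowered AMPKb1 (S182) by 0.18 alone, with 2 calls without replicate 1 and 0 without replicate 2 or replicate 3.

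Against each single inhibitor at 10 µM, the mixture of 10 µM of each was lower at the same sites. VAV1 (Y174) was at -1.28 ± 0.069 log2 against R406, -1.72 ± 0.068 against ibrutinib and -1.29 ± 0.069 against QNZ, and BTK (Y551) at -0.82, -1.18 and -0.94 in the same order. S6 (S240/S244) was -1.02 ± 0.084 against QNZ and -0.45 against ibrutinib, and CREB (S133) -0.27 against R406. IgM was higher than with ibrutinib by 0.24 and with QNZ by 0.26. In all 19 antibodies differed from R406 (3 higher, 16 lower), 25 from ibrutinib (9 and 16) and 26 from QNZ (9 and 17). Of the BCR list 8, 7 and 8 were lower and 0 higher (8, 8 and 8 adjusted over the list alone; camera adjusted p = 5.1e-06, 7.3e-06 and 1e-05). The count against ibrutinib was 16 without replicate 1 and 14 without replicate 2, and that against QNZ 17 without replicate 3. The splits were 7 and 13, 20 and 11, and 12 and 16 with total counts only, and 2 and 16, 2 and 20, and 4 and 21 with scaling on total-protein antibodies.

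Whether the mixture did more or less than the sum of the single log2 effects was tested at 10 µM. SRC (Y416) fell less than the sum by 1.23 ± 0.071 log2, BTK (Y223) by 1.20 ± 0.111, LYN (SRC) (Y397) by 1.19 ± 0.083, JAK1 (Y1022/Y1023) by 0.88 ± 0.075 and CDK1 (T14/Y15) by 0.81 ± 0.079. Total PLCy2 lay below the sum, -0.37 ± 0.081. VAV1 (Y174) departed by 0.18 (adjusted p = 0.50) and BTK (Y551) by 0.13 (adjusted p = 0.78), neither past the threshold. Of 111 antibodies 13 departed, 12 above and 1 below the sum, and DESeq2 called 14. The BCR list had 8 departures above and 0 below, with the same counts adjusted over the list alone (camera adjusted p = 5.8e-07). For all 12 departures above the sum, the sum itself lay below the unstimulated DMSO level, by a median of -0.60 log2, while the measured median was -0.05 from that level. These 12 were chosen for lying above the sum, so the count does not decide whether the unstimulated level limited the falls. With total counts only 10 departed above and 16 below. Against the strongest single inhibitor in place of the sum, SRC (Y416) was at -0.13, LYN (SRC) (Y397) at -0.15 and JAK1 (Y1022/Y1023) at -0.22, past the threshold. BTK (Y223) at -0.063 and CDK1 (T14/Y15) at -0.087 did not pass there. Of 100 splits of the wells 5, the real one included, gave as many as 13 departures, with a highest other of 28. These splits exchanged wells that differ by inhibitor, so they do not decide whether chance gave the departures.

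**Figure D4:**
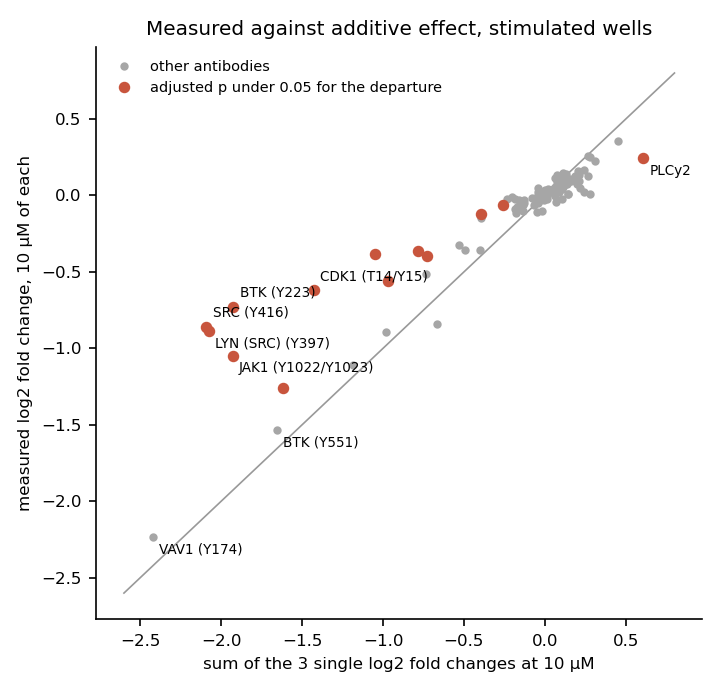
Sum of the 3 single log2 changes at 10 µM (x axis) against the measured log2 change with 10 µM of each inhibitor (y axis) for 111 antibodies, with the 13 past the threshold in red. SRC (Y416), BTK (Y223) and LYN (SRC) (Y397) lie above the line of equality by 1.23, 1.20 and 1.19.

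The stimulated wells with 10 µM of each inhibitor were set against unstimulated DMSO wells. This contrast joins what was left of the response with what the mixture did without the stimulus. In unstimulated cells the mixture moved IgM, BTK, GAPDH, PARP (D214), both S6 sites, CREB (S133) and ATF2 (T71) the same way, as given below. The stimulus effect under the mixture is the contrast free of that part. Of the 26 antibodies that the stimulus raised, 9 were still above the unstimulated level and 2 below it, and 6 rose with the stimulus under the mixture. IgM was higher by 0.72 ± 0.088 log2, BTK by 0.50, CD79a (Iga) by 0.46 ± 0.028, GAPDH by 0.35 and PARP (D214) by 0.32, while S6 (S240/S244) was at -0.85, S6 (S235/S236) at -0.40, CREB (S133) at -0.28 and ATF2 (T71) at -0.24. Of the BCR list 0 were higher and 2 lower, and of 7 DNA damage and apoptosis antibodies 5 were higher (camera adjusted p = 0.02, adjusted p = 0.11 with an estimated correlation). In all 31 differed, 17 higher and 14 lower, and 20 without replicate 1; with total counts only 15 were higher and 26 lower and with scaling on total-protein antibodies 15 and 29. The stimulus given under the mixture changed 13, 11 higher and 2 lower, with CD79a (Iga) at 0.40 ± 0.026 and IgM at 0.40 ± 0.086; without replicate 2 it changed 3 and without replicate 3 it changed 5. With total counts only 11 were higher and 7 lower.

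In unstimulated cells the mixture of 10 µM of each lowered S6 (S240/S244) by 0.78 ± 0.082 log2 (adjusted p = 8.5e-10), S6 (S235/S236) by 0.36 ± 0.039, ATF2 (T71) by 0.23 ± 0.056, CREB (S133) by 0.16 ± 0.037 and STAT3 (S727) by 0.12 ± 0.040. IgM rose by 0.32 ± 0.088, BTK by 0.21, GAPDH by 0.19 ± 0.043, PARP (D214) by 0.16, BIM by 0.15 and PKC-b1 by 0.15. That made 6 higher and 5 lower, with 0 of 14 BCR antibodies and 2 of 10 PI3K-AKT-mTOR antibodies changed (camera adjusted p = 0.023 for the latter). The count was 5 without replicate 1, 5 without replicate 2, 7 without replicate 3 and 5 with those conditions alone in the fit; with scaling on total-protein antibodies 5 were higher and 9 lower. The difference between the mixture's effects in stimulated and unstimulated cells passed for 21 antibodies, 4 higher and 17 lower, and with total counts only for 39 higher and 15 lower.

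Median removal of the stimulus effect was computed over the 11 antibodies that the stimulus raised by more than 0.5 log2. On the combination plate it was 99.0% (range 88.6% to 118%) with 10 µM of each inhibitor, 87.3% with 2.5 µM and 75.2% with 1 µM of each. Singles at 10 µM removed 52.3% with R406 (range 16.0% to 93.4%), 50.5% with ibrutinib (15.5% to 91.2%) and 70.6% with QNZ (37.9% to 86.5%). On the dose plates the values over 0.1, 1, 10 and 100 µM were 21.0%, 16.9%, 26.4% and 87.3% with ibrutinib, 23.1%, 40.9%, 63.7% and 63.7% with R406 and 41.1%, 45.7%, 44.3% and 78.9% with QNZ. Ranges were wide there too, for ibrutinib at 1 µM from -7.26% to 83.0%, with 8 of the 11 antibodies lowered past the threshold. The stimulus effect on the dose plates also holds the difference between plates. At 10 µM the medians on the dose plates and the combination plate were unlike, 26.4% and 50.5% for ibrutinib, 63.7% and 52.3% for R406, and 44.3% and 70.6% for QNZ.

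Single-inhibitor changes at 10 µM were measured on 2 plates in stimulated cells, a dose plate and the combination plate. Across 107 antibodies, which are not independent replicates, r was 0.935 for R406, 0.924 for ibrutinib and 0.860 for QNZ, and rho 0.555, 0.657 and 0.485. Called in the same direction on both plates were 22, 19 and 19 antibodies, with 19, 17 and 17 of them lower, and 1, 0 and 0 went in opposite directions. On the dose plates the total count per well did not differ from DMSO after adjustment over the 16 conditions of a plate (exact permutation test, two-sided, 3 against 12 wells, smallest possible p = 0.0022). The lowest unadjusted p was 0.00879 for QNZ at 10 µM in stimulated cells, with mean totals of 117709 and 194263 in DMSO (adjusted p = 0.141).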

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

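The tests of the mixture's difference between stimulated and unstimulated cells, of other splits except those for adding an inhibitor to a pair and for mixtures against each other, of the undescribed inhibitor, of the sister wells in the BIM pattern, of the shared plate row and of QNZ on the combination plate were chosen only after the result was seen.

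Inhibitor effects that differed between stimulated and unstimulated cells, by a test of the difference itself, are listed here because of that difference. Sites raised by the stimulus had more room to fall, so a more negative value does not by itself show a different action. For ibrutinib 23 antibodies differed, at 10 µM with BTK (Y223) at -0.62 ± 0.058 log2, SRC (Y416) at -0.59 ± 0.037, LYN (SRC) (Y397) at -0.59 ± 0.047, SYK (Y525/Y526) at -0.35 ± 0.074, CDK1 (T14/Y15) at -0.35 ± 0.042 and CD79a (Iga) at 0.094 ± 0.032. For R406 22 differed, with VAV1 (Y174) at -0.72 ± 0.064, LYN (SRC) (Y397) at -0.71 ± 0.048, BLNK (SLP-65) (Y84) at -0.65 ± 0.041, SRC (Y416) at -0.59 ± 0.037, BTK (Y551) at -0.58 ± 0.059 and CREB (S133) at 0.20 ± 0.040. For QNZ 24 differed, with VAV1 (Y174) at -0.64 ± 0.070, LYN (SRC) (Y397) at -0.59 ± 0.052, BLNK (SLP-65) (Y84) at -0.57 ± 0.044, BTK (Y223) at -0.56 ± 0.065 and SRC (Y416) at -0.54 ± 0.041. Of 100 splits of the same wells, 4, 2 and 2 gave as many for the 3 inhibitors (highest other 37, 23 and 24). These shares count the real grouping and are under the bound of 0.05. At least 1 other split of each gave as many or more. Wells that differ by the stimulus were exchanged, so the splits hold real effects and do not decide whether chance gave these counts.

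For 10 µM of each inhibitor on the combination plate 21 antibodies differed between stimulated and unstimulated cells. VAV1 (Y174) stood at -2.14 log2, BTK (Y551) at -1.49, PYK2 (Y402) at -1.22, BLNK (SLP-65) (Y84) at -1.06 and LYN (SRC) (Y397) at -0.96, and PLCy2 at 0.29, CD79a (Iga) at 0.19, STAT6 at 0.16 and STAT3 at 0.14. Of 100 splits 11, the real one included, gave as many. The highest other split gave 48. The splits exchanged wells that differ by the stimulus, so they hold real effects and do not decide whether chance gave this count. The wells have a structure by condition, and what raised the highest other split was not tested.

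A signal in wells outside the comparisons concerned the inhibitor named iPI3Kd, for which the F-test called 4 antibodies without and 6 with the stimulus. The 4 were CDK1 (T14/Y15), SRC (Y416), p90RSK1 (T359) and AKT (S473), with CDK1 (T14/Y15) at 0.12 ± 0.026 log2 at 0.1 µM. The 6 were BTK (Y223), at 0.22 ± 0.038 at 100 µM, CREB (S133), at 0.10 ± 0.021, MAPK p38 (T180/Y182), at 0.12 ± 0.028, STAT6 (Y641), ERK1/2 and AKT (T308). All were named after their values were seen.

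BIM was high in 1 well of R406 at 100 µM, at the same position of both dose plates, at a CPM value of 27229 against 6856 ± 302.8 (SD, 12 wells) in DMSO without and 14186 against 6350 ± 171.8 with the stimulus. A response to the inhibitor would have raised the other 2 wells, whose mean lay at most 0.0314 log2 from DMSO. Low depth is argued against by the wells' totals, the smaller at 0.861 of the plate median. An excess of this antibody's barcode at that plate position may be the source, since 0 other antibodies in the well differed by over 0.5 log2 from the sister wells. It was not found how such an excess arose.

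At 100 µM QNZ changed 55 antibodies in unstimulated cells, in wells with low totals. The controls GAPDH, at 0.27, Isotype Rabbit IgG, at -0.17, and Histone H3, at -0.16, were among them. The trend of control wells on depth gave at least 50% of the change for 1.82% of these antibodies, which argues against depth as the whole cause. The plate row is argued against by 0 antibodies changed at 100 µM of iPI3Kd in the same row. A response to the inhibitor remains as a hypothesis, since 87.3% of the antibodies (48 of 55) moved the same way on the stimulated plate, in other wells with other controls, although the log2 changes of all antibodies on the 2 plates correlated at only 0.458. How much of the falls came from unspecific binding was not tested. An effect on cell number or viability was not measured.

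At 0.1 µM QNZ lowered 11 of 14 BCR antibodies in stimulated cells. Plate columns are argued against, since 10 were lower against the 3 DMSO wells of the same columns. The plate row as the whole cause is argued against by iPI3Kd at 0.1 µM in the same row, which lowered 1 of the 14. Falls at this dose were not particular to QNZ. Of all 107 antibodies ibrutinib and R406 each lowered 14 there, and QNZ 19. With scaling on total-protein antibodies 11 were lower. That scaling moved values down here, GAPDH from -0.11 to -0.12, so it could hardly end a fall and does not decide on scaling. Total counts only moved GAPDH the other way, to -0.056. A response in stimulated cells remains as a hypothesis, since all 11 were lower at 10 µM of QNZ on the combination plate. Whether QNZ acts on these kinases or on a step above them was not tested.

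Other splits of the same wells were counted for every model result, 100 drawn where there were more. On the unstimulated plate as many antibodies came up in 2 splits for ibrutinib (11, highest other 15), 4 for R406 (10, 10) and 1 for QNZ (61, 47), and on the stimulated plate in 1 each for ibrutinib (40, 35), R406 (42, 27) and QNZ (79, 40). For the stimulus it was 1 (62, 49). Between inhibitors it was 1, 1 and 3 without the stimulus (6, 51 and 43, highest other 5, 46 and 46, in the order R406 against ibrutinib, QNZ against ibrutinib and R406 against QNZ) and 1, 1 and 1 with it (25, 57 and 60, highest other 22, 43 and 55). For DMSO against PBS with the stimulus it was 4 (4, 7), and for the F-test over equal mixtures 1 (37, 36). Each number of splits includes the real grouping, so 1 means that no other split drawn gave as many. The shares for these are all under the bound of 0.05, which argues against a random grouping of the wells. From 100 draws, of wells that may be technical replicates, chance is not excluded. Other splits gave as many or more for ibrutinib, R406 and R406 against QNZ without the stimulus and for DMSO against PBS with it. For the stimulus the groups are also the plates, which the splits do not separate. For DMSO against PBS without the stimulus all 100 splits gave at least the real 0, with a highest of 3. For the departure from the sum 5 splits gave as many as the real 13, and the highest other gave 28. The splits exchanged wells that differ by inhibitor, so they hold real effects and do not decide whether chance gave the departures. In data simulated without single effects 0.385% of unchanged antibodies were called for the departure. The wells have a structure by condition, and what raised that split was not tested.

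Comparisons of 3 wells with 3 have 10 splits, too few for a share under 0.05. The real count and the highest other were 45 and 1 for the stimulus on the combination plate, 27 and 0, 33 and 0, and 44 and 0 for equal mixtures of 1, 2.5 and 10 µM. They were 38 and 0, 31 and 0, and 41 and 1 with 5 µM of R406, ibrutinib or QNZ. For the pairs 2.5+2.5+0, 2.5+0+2.5 and 0+2.5+2.5 they were 27 and 0, 30 and 0, and 28 and 0, for single R406, ibrutinib and QNZ 32 and 1, 20 and 0, and 21 and 0, and for the unstimulated mixture 11 and 4. Against single R406, ibrutinib and QNZ the mixture gave 19 and 0, 25 and 3, and 26 and 0. Adding QNZ, ibrutinib or R406 to a pair gave 9 and 0, 0 and 0 (in 10 of 10 splits), and 8 and 8 (2 splits). The contrasts between mixtures gave 4 and 0, 5 and 0, and 1 and 1 (2 splits), the mixture against unstimulated DMSO 31 and 14, and the stimulus under the mixture 13 and 0.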

How the results depend on the processing

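Chosen only after results were seen were the tests with own DMSO wells, plate column as a block, log10 total as a covariate and no wells under 0.5 of the plate median.

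Of 1990 counts of called antibodies under an alternative 1767 stayed within 1.5 times and the others moved; of 8479 values of named antibodies 7956 stayed, 402 lost and 105 gained a call and 16 reversed; of the list shifts against the other antibodies 454 stayed, 5 gained and 3 lost a call with an estimated correlation; and 46 of 46 total-count tests stayed. With fry, which tests whether a list moves on balance one way and compares it with no other antibodies, 97 lists passed that camera did not call, 12 called by camera did not pass and 353 agreed. The cause was not tested for moved values unless stated. The antibody filters removed nothing and so tested nothing. Leaving out wells under 0.25 of the plate median removed 1 DMSO well of the unstimulated plate and moved 2 counts, R406 at 1 µM from 1 to 2 and R406 against QNZ at 0.1 µM from 0 to 1; 5 named antibodies lost and 1 gained a call. An alternative with the upper or lower side of the plate was not run because conditions are nested in rows. Replicate numbers did not pair the wells (median r of same-numbered wells -0.0169, 0.0433 and 0.0601 on the 3 plates), and the replicate block moved 1 count by over 1.5 times, R406 against ibrutinib at 10 µM in unstimulated cells from 2 to 0, and ended the call of 1 named antibody, PI3K p110d (PIK3CD) with 1+1+5 at 0.15 (adjusted p = 0.052). In simulated data at this depth 68.0% of antibodies changed 1.1-fold were called for ibrutinib in stimulated cells, so smaller changes can go uncalled.

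Total counts only, which leaves composition in the scaling, gave 92 (ibrutinib) and 90 (R406) in stimulated cells, 101 for the stimulus on the dose plates and 65, 60 and 77 for the differences between plates. On the combination plate it gave 91 for the stimulus, 88 for the F-test, and 83, 87, 82, 85, 90 and 75 for 1+1+1, 2.5+2.5+2.5, 10+10+10, 5+1+1, 1+5+1 and 1+1+5. For 2.5+2.5+0, 2.5+0+2.5 and 0+2.5+2.5 it gave 84, 84 and 68, for 10+0+0, 0+10+0 and 0+0+10 it gave 65, 54 and 65, for the departure 26 and for the mixture's difference between stimulated and unstimulated cells 54. DMSO against PBS with the stimulus gave 7. It reversed PLCy2 (Y753) under R406 in stimulated cells to 0.054, PLCy1 (Y783) to -0.047, PLCy2 (Y753) to -0.12, PLCy2 (Y759) to -0.10 and TAK1 (T184/T187) to -0.12 for the stimulus on the dose plates, and PLCy1 (Y783) to -0.066 and IkB to -0.10 on the combination plate. With 10+10+10 it reversed PKC-b1 (T642) to 0.086, NFkB RelB (S552) to 0.077, NFkB p50 to 0.10 and TAK1 (T184/T187) to 0.10.

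Against the strongest single inhibitor in place of the sum, departures turned to SRC (Y416) -0.13, LYN (SRC) (Y397) -0.15 and JAK1 (Y1022/Y1023) -0.22. In that contrast these passed the threshold (adjusted p = 0.016, 0.018 and 0.00016). BTK (Y223) at -0.063 (adjusted p = 0.74) and CDK1 (T14/Y15) at -0.087 (adjusted p = 0.25) did not pass. The change of reference lowers these departures by construction, but it does not fix their sign. Without the 100 µM wells the F-tests lost that dose and gave 3 (ibrutinib), 5 (R406) and 14 (QNZ) in unstimulated and 46 (QNZ) in stimulated cells. With only the compared conditions in the fit, which leaves fewer wells for the spread, the counts were 5 and 6 for ibrutinib and R406 in unstimulated cells, 5 for the unstimulated mixture, 14 for 10+10+10 against ibrutinib, 11 for 5+1+1 against 1+5+1 and 19 for 10+10+10 against unstimulated DMSO. For R406 in unstimulated cells own DMSO wells gave 18, plate column as a block 16 and no wells under 0.5 of the plate median 16. R406 against ibrutinib in unstimulated cells gave 1 with limma on the deposited signal, 3 with the column block and 11 without wells under 0.5 of the median. DMSO against PBS gave 2 without and 8 with the stimulus under the column block, and with the stimulus 7 with the left or right side of the plate and 2 with the log10 total.

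Without replicates 1, 2 and 3, with fewer wells, the counts were 3, 4 and 13 for ibrutinib in unstimulated cells. R406 against ibrutinib gave 2, 1 and 1 without and 23, 16 and 18 with the stimulus, QNZ against ibrutinib 33, 28 and 40 and 48, 35 and 37, R406 against QNZ 29, 27 and 39 and 48, 37 and 43, and DMSO against PBS 0, 0 and 1 and 4, 0 and 0. For 1+1+5 they were 38, 26 and 26, for the unstimulated mixture 5, 5 and 7, for 10+10+10 against ibrutinib 16, 14 and 18 and against QNZ 23, 19 and 17. For 2.5+2.5+2.5 against 2.5+2.5+0, 2.5+0+2.5 and 0+2.5+2.5 they were 14, 6 and 8, 0, 0 and 2, and 14, 7 and 8. For 5+1+1 against 1+1+5 they were 2, 1 and 4, for 1+1+5 against 1+5+1 they were 2, 0 and 0, for 10+10+10 against unstimulated DMSO 20, 31 and 23, and for the stimulus under the mixture 9, 3 and 5.

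Single doses moved too. QNZ at 10 µM in unstimulated cells, 13 antibodies, gave 25 with limma, 36 with PBS wells as control, 34 with both vehicles, 25 with own DMSO wells and 3 with only the compared conditions. R406 in stimulated cells gave 5 at 0.1 µM (from 14) and 12 at 1 µM (from 30) with own DMSO wells. DESeq2 gave 7 for R406 against ibrutinib at 1 µM in stimulated cells (from 16).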

Other observations

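Chosen only after results were seen were the tests of the IgM signal under the mixture and of sites below the unstimulated level; the count of additive predictions below that level was chosen before its result.

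IgM and total CD79a (Iga) stayed raised by the stimulus under the mixture. IgM, which the stimulating antibody also binds, rose with the stimulus by 0.24 log2 on the dose plates and 0.36 on the combination plate, and under 10 µM of each inhibitor it still rose with the stimulus by 0.40 ± 0.086. On the dose plates IgA also rose, by 0.049, and IgD and IgG went the other way, at -0.071 and -0.087. Total CD79a (Iga), the signalling chain of the receptor, rose by 0.40 ± 0.026 with the stimulus under the mixture, while its phosphorylated form, CD79a (Iga) (Y182), fell by 0.84 ± 0.049 with the mixture against stimulated DMSO. Whether the antibodies reached more epitopes or more protein was present was not tested.

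Whether the departures above the sum come from a floor at the unstimulated level was left open. For 12 of 12 antibodies departing upwards the additive prediction lay below the unstimulated DMSO wells, but these antibodies were chosen for lying above the sum, so this count decides nothing. A strict floor for every site is argued against, since 2 of the 12 were measured below the unstimulated DMSO wells past the threshold, JAK1 (Y1022/Y1023) at -0.16 ± 0.044 and PLCy2 (Y753) at -0.11 ± 0.032 log2. A test at lower doses of each single inhibitor on the same plate would separate a floor from an interaction; the combination plate holds singles at 10 µM only.

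Single wells rarely stood apart. Of 15267 values in conditions of 3 wells 8 differed by over 0.5 log2 from the mean of their sister wells, and 6 of these belonged to BIM in the 2 R406 conditions at 100 µM. On the unstimulated dose plate the lowest total was 51056, in a DMSO well. For iPI3Kd, antibodies past the threshold at 0.1, 1, 10 and 100 µM were 2, 0, 0 and 0 without the stimulus and 4, 0, 0 and 6 with it, by edgeR, with 15, 9, 7 and 13 and 11, 10, 5 and 18 at an unadjusted p under 0.05.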
